A study of Arabidopsis thaliana with 3 samples.

How the data were processed

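RNA-seq was performed on whole seedlings of Arabidopsis thaliana harvested at 14 days, in 3 genotypes: the wild type Col-0, the pwo1 mutant and the crwn1 crwn2 double mutant. The series' design text gives 3 biological replicates per genotype, RNA isolated with a column kit and paired-end sequencing of TruSeq v2 libraries. Seeds were stratified for 2 days before sowing on MS plates in long days. Each genotype was recorded as a single sample, so values per library, library totals and the spread between replicates were not used here.

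The files were 2 tables of the authors' own comparisons, one per mutant. Per the file headers, each row gives a log2 fold change and a p-value from edgeR and a log2 fold change and a p-value from Cuffdiff. Per the submitters' processing notes, the tools included Trimmomatic 0.35, FastQC 0.10, TopHat2 2.0.12, HTSeq 0.6.1, edgeR 3.3, Cufflinks 2 and Cuffdiff 2.2.1, with the genome build TAIR10. The notes used here assign no roles or order to these tools. The normalization, the filter on low counts, the threshold for listing a gene and whether counting used the strand are not given in the sources used here.

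From the values, the tables hold only genes that passed in both tools. The largest p-value in the authors' deposited table for pwo1 was 0.00386 by edgeR and 0.00455 by Cuffdiff, and in that for crwn1 crwn2 it was 0.00585 and 0.0074. Cuffdiff's smallest p-value, 5e-05, was shared by 596 genes in the deposited pwo1 table and 1092 genes in the deposited crwn1 crwn2 table, so these p-values appear to be unadjusted. Genes that were tested and not listed were not analysed here. A gene that is not listed is therefore not shown to be unchanged. The depth behind each value is unknown, and no interval or detection limit that needs counts was computed.

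Fold changes are given as mutant over Col-0. The headers name Col first, and the sign was checked on the mutated genes: CRWN1 and CRWN2 are both negative in the authors' deposited crwn1 crwn2 table. PWO1 is not among the genes listed for pwo1, so the sign of that table rests on its header having the same form. The authors' log2 fold changes by edgeR are the main values. Those of Cuffdiff correlated with them at r = 0.997 across 1238 genes in the deposited pwo1 table and at 0.98 across 1934 genes in the deposited crwn1 crwn2 table. The sign differed for 1 gene, in crwn1 crwn2. For 1 gene per table the Cuffdiff fold change was infinite or written as a spreadsheet error, and was left out. Gene names came from a reference of build TAIR10.1, which held 1236 of the 1239 identifiers listed for pwo1 and 1933 of the 1935 listed for crwn1 crwn2. Because that build differs in name from the authors' TAIR10, no coordinates are given, and the chromosome is the digit after AT in each identifier.

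The following choices were fixed before the data were examined. A gene was to count as changed at an adjusted p under 0.05, but the tables have no such column, so a gene counted as changed when the authors' table lists it. For 17 lists with 253 members in all, chosen by pathway or organ, the number of listed members was compared with the other genes by a one-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 34 tests. The design also named a count adjusted over the list alone, for which members not listed were given a p of 1. Listed members already had small p-values, so this count equals the number listed almost by construction and adds no separate evidence. The background for Fisher's test should be the genes tested by the authors. As these are unknown, the 27550 protein-coding genes of the reference were used, which makes the enrichment p-values too small, and an assumed background of 15000 genes was tried. Members of a list can also change together, and the tests treat them as independent. Whether members leaned to one direction was tested within each table, against the other listed genes, by a two-sided Fisher's exact test, a test added after the tables were seen. The named genes are the mutated genes, the 8 with the largest fold change in each direction per table, up to 4 members of each list with the smallest p-value by the authors' edgeR test, and 5 genes shared between the mutants per direction and 5 with opposite directions, by the smaller of the absolute fold changes. Members outside this rule were named after their values were seen, to complete a group. No adjusted p was in the tables, so an upper bound was computed by Benjamini-Hochberg adjustment of the listed p-values over all 38082 genes of the reference. This bound was under 0.05 for 945 of the 1239 genes listed for pwo1 and 1604 of the 1935 listed for crwn1 crwn2, so the other listed genes are not shown to pass the planned threshold.

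For genes in both tables, a standard error was implied from each p-value and fold change by edgeR in the authors' deposited tables under a normal approximation. It was used to test the difference between the mutants, with Benjamini-Hochberg adjustment over 508 genes and no allowance for the shared Col-0 libraries (an alternative correlates the errors at 0.5), and to simulate those shared libraries. In 200 draws, errors of the 2 contrasts were correlated at 0.5, as for equal group sizes. The scripts were tested on simulated data of 27550 genes with 200 changed genes: with the errors of the pwo1 table, 76% of genes changed by 1 on the log2 scale and 99% of those changed by 2 were recovered. With the errors in crwn1 crwn2 the shares were 69% and 96%. False calls made up 2.78% of calls for pwo1 and 7.30% for crwn1 crwn2, at an adjusted p under 0.05. The simulated errors were normal, of known size and drawn from those of listed genes. These shares therefore do not measure the sensitivity or false calls of the authors' tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives were a 2-fold threshold, stricter p-values, nuclear protein-coding genes alone, other backgrounds and Cuffdiff's fold changes.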

Results

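The transcriptomes of 14-day-old whole seedlings were compared between the wild type Col-0 and mutants described by the submitters as affecting nuclear size. PWO1 is a PWWP-domain protein linked to Polycomb repression. CRWN1 and CRWN2 are coiled-coil proteins of the plant nuclear lamina. Each mutant was compared with Col-0, with 3 biological replicates per genotype according to the series' design text. The values are fold changes and p-values of the authors' own tests, so no spread between replicates accompanies them. The p-values rest on the spread between the stated replicates as the authors' tools modelled it, and that spread cannot be read from them. The depth of each library was not analysed here. The authors' deposited tables list 1239 genes for pwo1 and 1935 genes for crwn1 crwn2.

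The first comparison asked which genes differ between pwo1 and Col-0. Of the 1239 genes, 527 were higher and 712 were lower in pwo1. Genes of iron uptake were among the most strongly raised, and some genes of photosynthesis, jasmonate synthesis, aliphatic glucosinolate synthesis and salicylic acid responses were among those that fell. The floral repressor FLC was lower, with a log2 fold change of -2.16 in the authors' deposited table (edgeR p = 2.98e-10). The median absolute log2 fold change of the authors' deposited table was 0.83, and 183 genes rose and 247 fell by at least 2-fold. PWO1 itself (AT3G03140, chromosome 3) was not among the listed genes, so the mutated gene does not check this comparison or the sign of its fold changes. That sign is read from the header alone, and each direction given for pwo1 would turn with it. Of the list of 3 mutated genes, 0 were listed for pwo1.

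Of 20 genes in the copper and iron list, 7 rose in pwo1 and none fell, a count of 7 also when adjusted over the list alone. This was more than the 0.90 expected from the reference background (Fisher's exact test, adjusted p = 9.50e-05), and the direction differed from that of the other listed genes (Fisher's exact test, adjusted p = 0.019). In the authors' deposited table the ferrous iron transporter IRT1 (AT4G19690) had a log2 fold change of 4.05 (edgeR p = 1.44e-19), and the ferric chelate reductase FRO2 (AT1G01580) one of 3.56 (edgeR p = 2.57e-22). The iron-deficiency transcription factors BHLH38, BHLH39 and BHLH100 had log2 fold changes of 3.34, 3.27 and 3.58 in the authors' deposited table. BHLH38 overlaps another annotated gene, BHLH38 and BHLH39 are neighbouring related genes, and how the counting treated reads common to them is not given in the sources used here. The ferritin gene FER1, which encodes an iron storage protein, also rose, by 1.06 in the authors' deposited table, as did the superoxide dismutase gene CSD1, by 0.81. FER1 and CSD1 overlap other annotated genes, which makes their values uncertain in both mutants. The largest rises of the authors' deposited table were 7.64 for AT3G12900, an iron-dependent oxygenase of coumarin synthesis, and 4.67 for CYP82C4, a cytochrome P450 of the same pathway. The authors' deposited table gave further rises of 3.70 for AT4G29770, a target of trans-acting small RNAs, 3.38 for the lipid transfer protein gene LTP4 and 3.38 for LEA7, a late embryogenesis abundant gene that overlaps another annotated gene.

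Of 30 salicylic acid and immune genes, 8 fell, 1 rose and 21 were not listed in pwo1, with all 9 also listed when adjusted over the list alone (Fisher's exact test for the number listed, adjusted p = 3.77e-05). A difference in direction from the other listed genes was not shown (Fisher's exact test, adjusted p = 0.42). The authors' deposited table gave -1.55 for LURP1 (edgeR p = 7.40e-14), -0.76 for DMR6, which encodes a salicylic acid hydroxylase, and -1.17 for WRKY54. EARLI1, a lipid transfer protein gene that overlaps another annotated gene and has close relatives beside it, rose by 1.04 in the authors' deposited table. Of 23 jasmonate and ethylene defence genes, 4 fell and none rose, again 4 when adjusted over the list alone (adjusted p = 0.048, Fisher's exact test). This call was lost with an assumed background of 15000 genes (adjusted p = 0.31), and a difference in direction from the other listed genes was not shown (adjusted p = 0.46, Fisher's exact test). They were the jasmonate synthesis genes AOS, LOX2 and AOC1, with log2 fold changes of -1.41, -1.01 and -0.57 in the authors' deposited table, and the repressor gene JAZ6, with -0.47.

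Of 10 glucosinolate genes, 4 fell and none rose in pwo1, 4 also when adjusted over the list alone (Fisher's exact test, adjusted p = 0.0024). No member passed a 2-fold threshold, and a difference in direction from the other listed genes was not shown (Fisher's exact test, adjusted p = 0.46). The regulators MYB28 and MYB29 had log2 fold changes of -0.67 and -0.98, and the enzymes CYP79F1 and BCAT4 of -0.85 and -0.71, in the authors' deposited table. In the leaf photosynthesis markers, 3 of 7 members fell and 1 rose, all 4 also when adjusted over the list alone (adjusted p = 5.43e-04, Fisher's exact test). No member passed a 2-fold threshold, and the direction was not shown to differ from that of the other listed genes (adjusted p = 0.98, Fisher's exact test). The authors' deposited table gave -0.97 for the chlorophyll-binding protein gene LHCB1.1, -0.76 and -0.75 for the chloroplast regulators GLK1 and GLK2, and 0.76 for the Rubisco small subunit gene RBCS2B. LHCB1.1 and RBCS2B have near-identical copies, so their values are uncertain. None of the 12 root markers and none of the 8 seed markers was listed, and the p-values of genes not listed were not analysed here.

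The circadian clock list held 7 of its 14 members, 5 lower and 2 higher, all 7 also when adjusted over the list alone (Fisher's exact test, adjusted p = 1.08e-05). The authors' deposited table gave -1.11 for CDF1, -0.77 for PRR7, -1.25 for PRR9 and -0.52 for GI, and 0.50 for the evening genes TOC1 and ELF4. Of 12 flavonoid genes, 3 rose and 1 fell, all 4 also when adjusted over the list alone (adjusted p = 0.0047, Fisher's exact test). Chalcone synthase CHS, CHI and F3'H had log2 fold changes of 1.75, 0.79 and 0.84 and LDOX of -1.30 in the authors' deposited table. The cold, drought and abscisic acid list split, with 2 members higher and 3 lower of 17, 5 when adjusted over the list alone (adjusted p = 0.0024, Fisher's exact test). RD29B and RAB18, genes induced by abscisic acid, had log2 fold changes of 2.24 and 1.54 in the authors' deposited table, whereas GOLS2 and COR15B had -1.69 and -1.10. The calls for the clock and flavonoid lists were lost with a 2-fold threshold (adjusted p = 0.074 and 0.061, Fisher's exact test), and that for the cold list under a stricter p (adjusted p = 0.23, Fisher's exact test). BCAT4, CHS, COR15B and RAB18 overlap other annotated genes, which makes their values uncertain.

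Among 24 flowering genes 3 were listed, 3 also when adjusted over the list alone, which did not exceed the background (Fisher's exact test, adjusted p = 0.21). Besides FLC they were the repressor SVP, at -0.80, and the floral identity gene SEP3, at 1.46, in the authors' deposited table. FLC overlaps another annotated gene, and without knowledge of strand its reads cannot be told from those of an overlapping transcript. Of the seed and meristem regulators only DOG1 was listed, at -1.14 in the authors' deposited table (1 of 10, 1 also when adjusted over the list alone, adjusted p = 0.70, Fisher's exact test). HSP70 was the one heat shock gene of 9 listed, at 0.88 in the authors' deposited table (1 also when adjusted over the list alone, adjusted p = 0.68, Fisher's exact test). None of the 18 nuclear lamina and envelope genes, the 21 Polycomb group genes or the 15 cell cycle and DNA damage genes was listed for pwo1. The largest falls of the authors' deposited table were -8.63 for the F-box gene AT5G56370, -5.16 for AT1G77960 of unknown function, -3.14 for AT1G50970, -3.13 for the defensin-like gene AT2G16367 and -3.13 for the transposon gene AT3G29120. AT5G05060 followed with -2.98, BPM6 with -2.89 and the starch-related orphan gene QQS with -2.85 in the authors' deposited table. Cuffdiff gave no readable fold change for AT5G56370, so the size of its fall is uncertain.

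The second comparison asked which genes differ between crwn1 crwn2 and Col-0. Both mutated genes were lower in the double mutant. In the authors' deposited table CRWN1 (AT1G67230, chromosome 1) had a log2 fold change of -3.03 (edgeR p = 1.90e-89) and CRWN2 (AT1G13220, chromosome 1) one of -2.42 (edgeR p = 3.05e-39). Cuffdiff gave -1.57 for CRWN2 in the authors' deposited table. Of the list of 3 mutated genes these 2 were listed, 2 also when adjusted over the list alone (Fisher's exact test, adjusted p = 0.040, and 0.13 with an assumed background of 15000 genes). The list was made of the mutated genes themselves, so this test checks the genotype and is no evidence on a pathway. Of the 1935 genes, 1093 were higher and 842 lower, a share of 56.5% higher. Among genes changed by at least 2-fold, 552 were higher and 230 lower, a share of 70.6%. All listed members of the salicylic acid and immune list rose, iron-deficiency regulators rose, and all listed cold-response genes fell.

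Of the 30 salicylic acid and immune genes, 22 rose and none fell in crwn1 crwn2, 22 also when adjusted over the list alone. This compares with 2.11 expected (Fisher's exact test, adjusted p = 4.32e-18), and the direction differed from that of the other listed genes (Fisher's exact test, adjusted p = 7.98e-05). In the authors' deposited table the median log2 fold change of these 22 genes was 1.87. The receptor kinase gene FRK1 had a log2 fold change of 4.07 (edgeR p = 1.35e-23), the regulator SARD1 one of 2.37 (edgeR p = 7.37e-23), DMR6 one of 1.96 and LURP1 one of 1.78 in the authors' deposited table. The pathogenesis-related gene PR1 was at 4.03 (3.44 by Cuffdiff), the salicylic acid synthesis genes ICS1 and PBS3 at 1.75 and 1.99, and the immune regulators EDS1 and PAD4 at 1.29 and 1.52 in the authors' deposited table. FRK1 and SARD1 overlap other annotated genes, as does BHLH101 of the iron list. Jasmonate and ethylene genes were listed for 2 of 23 members, both lower and both also when adjusted over the list alone (adjusted p = 0.79, Fisher's exact test). These were AOS, at -1.28, and VSP2, at -2.21, in the authors' deposited table.

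**Figure D1:**
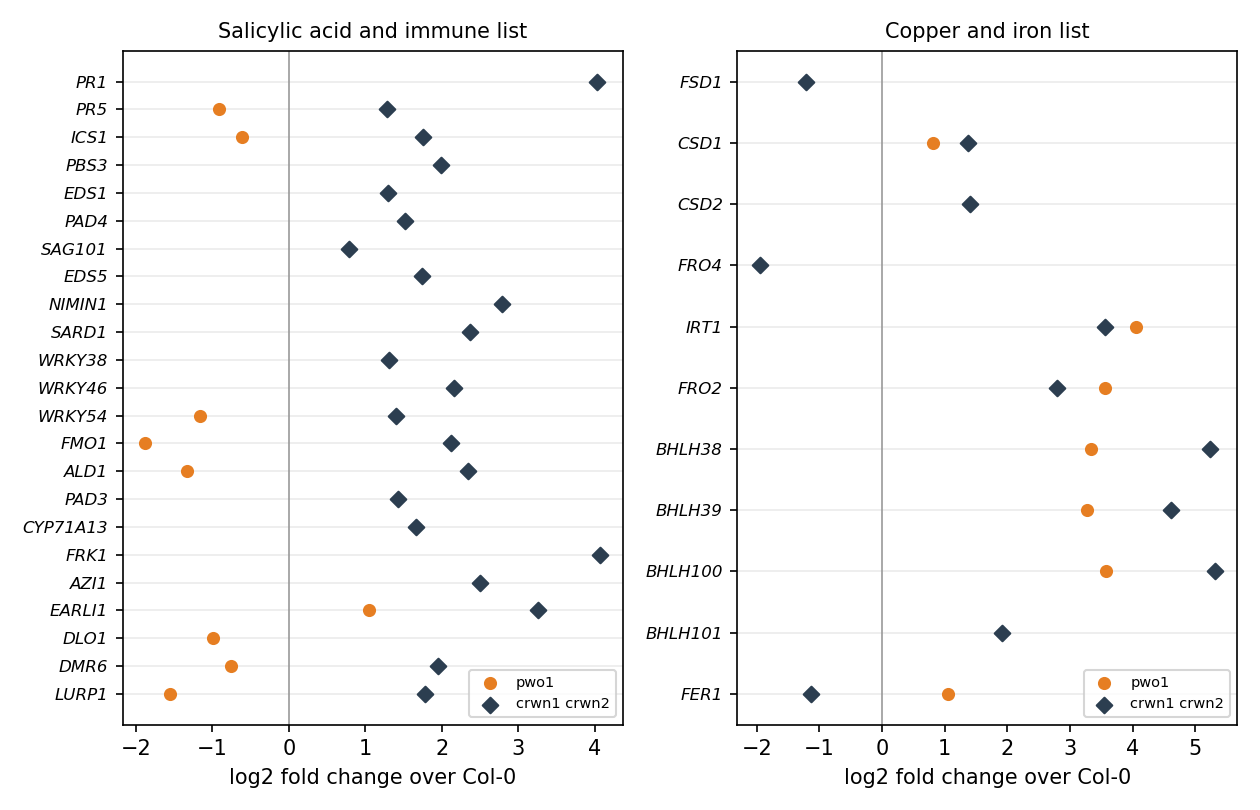
Log2 fold change over Col-0 (horizontal axis) of each member of the salicylic acid and immune list (left) and of the copper and iron list (right) that the authors' tables list for pwo1 (circles) or crwn1 crwn2 (diamonds), with 1 value per gene and mutant and no error bars because replicate values were not used. A missing symbol means that the gene was not listed for that mutant. All 22 immune members listed for crwn1 crwn2 lie above 0, while 8 of the 9 listed for pwo1 lie below 0.

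The copper and iron list held 11 of 20 members in crwn1 crwn2, 8 higher and 3 lower, all 11 also when adjusted over the list alone (Fisher's exact test, adjusted p = 3.15e-07). The authors' deposited table gave 5.31 for BHLH100, 5.23 for BHLH38, 4.62 for BHLH39 and 1.92 for BHLH101. IRT1 and FRO2 were at 3.55 and 2.80 in the authors' deposited table. The copper and zinc superoxide dismutase genes CSD1 and CSD2 rose by 1.37 and 1.40, while the iron superoxide dismutase gene FSD1 was at -1.21, the reductase gene FRO4 at -1.95 and FER1 at -1.13 in the authors' deposited table. Cold, drought and abscisic acid genes fell, with 8 of 17 members lower and none higher, 8 also when adjusted over the list alone (adjusted p = 5.43e-05, Fisher's exact test). The direction differed from that of the other listed genes (Fisher's exact test, adjusted p = 0.015). COR15B had a log2 fold change of -2.46, KIN2 of -1.73 (-1.11 by Cuffdiff), the abscisic acid synthesis gene NCED3 of -1.63 and RD29A of -1.24 in the authors' deposited table. COR15B and KIN2 have close neighbouring relatives, and COR15B overlaps another annotated gene.

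In the glucosinolate list 5 of 10 members fell and 1 rose, all 6 also when adjusted over the list alone (Fisher's exact test, adjusted p = 9.50e-05). This call was lost with a p under 0.001 in both tools (adjusted p = 0.21, Fisher's exact test). MYB29 was at -1.22, CYP79B3 at -0.64, BCAT4 at -0.67 and CYP83B1 at 0.76 in the authors' deposited table. Clock genes were listed for 3 of 14 members, 2 higher and 1 lower and all 3 also when adjusted over the list alone (adjusted p = 0.17, Fisher's exact test). The morning genes LHY and CCA1 were at 0.97 and 0.72 and GI at -0.59 in the authors' deposited table. Of 12 flavonoid genes 2 rose, 2 also when adjusted over the list alone (adjusted p = 0.43, Fisher's exact test), namely CHS at 1.73 and CHI at 1.02 in the authors' deposited table. Of 24 flowering genes 2 were listed, 2 also when adjusted over the list alone (adjusted p = 0.79, Fisher's exact test). The flowering inducer FT was at 1.65 and SVP at -0.75 in the authors' deposited table. HSP90.1, 1 of 9 heat shock genes, was at 1.26 in the authors' deposited table, and GLK1, 1 of 7 leaf markers, was at -0.73. HSP90.1 and GLK1 also counted when adjusted over the list alone, and neither list exceeded the background, with adjusted p = 0.79 and 0.71 by Fisher's exact test. PARP2 was the 1 listed member of 15 cell cycle and DNA damage genes, at 0.70 in the authors' deposited table, and 0 members passed when adjusted over the list alone (adjusted p = 0.98, Fisher's exact test).

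None of the 18 nuclear lamina and envelope genes, the 21 Polycomb group genes, the 10 seed and meristem regulators, the 12 root markers or the 8 seed markers was listed for crwn1 crwn2, and the p-values of genes not listed were not analysed here. The largest rises in the authors' deposited table were 9.94 for AT1G27565 of unknown function, 8.85 for AT3G01345, 6.38 for the copia-like transposon gene AT5G35935 and 5.65 for the inositol oxygenase gene MIOX4. After BHLH100, BHLH38 and BHLH39, given above, AT1G62420 followed with 4.29 in the authors' deposited table. The largest falls of the authors' deposited table, apart from genes named above, were -5.54 for AT5G57345, -4.34 for the cupin gene AT5G38910, -3.30 for AT1G77960, -2.43 for SP1L2, a relative of the microtubule-associated SPIRAL1, and -2.38 for the myrosinase-binding protein gene MBP1. AT5G57345, AT1G77960 and SP1L2 overlap other annotated genes. Cuffdiff's fold change for AT1G27565 was infinite, so the size of its rise is uncertain.

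The third comparison asked how far the changes of the 2 mutants overlapped. The tables shared 508 genes, which were 41.0% of those listed for pwo1 and 26.3% of those listed for crwn1 crwn2. Of these, 301 were lower in both mutants, 162 were higher in both and 45 went in opposite directions. These shares rest on the sign of the pwo1 table, read from its header alone, and with that sign turned 463 genes would be opposite and 45 alike. Independent lists drawn from 27550 genes would share 21.8 genes lower in both and 20.9 higher in both (one-sided Fisher's exact p = 3.79e-277 and 1.03e-98). With an assumed 15000 tested genes the expected numbers were 39.97 and 38.4 (one-sided Fisher's exact p = 3.03e-200 and 1.29e-60).

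With the sign of the pwo1 table as read, genes raised in both mutants were led by iron-deficiency genes, and with it turned the genes of this paragraph would be opposite between the mutants. The authors' deposited tables gave CYP82C4 4.67 in pwo1 and 3.73 in crwn1 crwn2, IRT1 4.05 and 3.55, BHLH100 3.58 and 5.31, BHLH38 3.34 and 5.23, and BHLH39 3.27 and 4.62. Genes lowered in both were led by AT1G77960, with -5.16 in pwo1 and -3.30 in crwn1 crwn2, and MBP1, with -2.60 and -2.38 in the authors' deposited tables. The fumarase gene FUM2 had -1.96 and -2.13, the auxin-response gene SAUR22 -1.95 and -2.10, and UNE15 -1.85 and -2.26 in the authors' deposited tables. AT1G77960 and UNE15 overlap other annotated genes.

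Among the 45 genes with opposite directions, 38 were lower in pwo1 and higher in crwn1 crwn2, and 7 were the reverse. Independent lists drawn from 27550 genes would give 28.2 and 16.1, and from an assumed 15000 genes 51.9 and 29.6, so 38 lies above or below the expected number depending on the background. The difference between the mutants passed an adjusted p of 0.05 for 61 of the 508 shared genes, namely all 45 opposite genes and 16 with the same direction. With errors correlated at 0.5 through the shared Col-0 libraries it passed for 96 genes, 45 opposite and 51 with the same direction. For the opposite genes this follows almost by construction, because both values had passed the authors' tests. The immune gene FMO1, a monooxygenase of systemic resistance, was at -1.88 in pwo1 and 2.12 in crwn1 crwn2 in the authors' deposited tables. AT3G28510, an ATPase gene, was at -2.77 and 1.68, the haem oxygenase gene HO3 at -1.88 and 1.67, LURP1 at -1.55 and 1.78, and AT1G24147 at -1.52 and 1.50 in the authors' deposited tables. HO3 overlaps another annotated gene.

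Across the 508 shared genes the log2 fold changes correlated with Pearson's r = 0.78 and Spearman's rho = 0.72, across genes, which are not independent replicates. With the sign of the pwo1 table turned, r would be -0.78, rho -0.72 and the covariance given here -1.23. Both comparisons used the Col-0 libraries, which induces a correlation by itself. In simulations with no effect in either mutant, an average of 9.75 genes of 27550 passed in both contrasts, all in the same direction and with a mean r of 0.98 among them. When effects as strong as the listed ones were placed independently in each mutant, the simulations gave 43.0 genes with the same direction on average and at most 61, against 463 observed, and a mean r of 0.156. Those numbers are for 27550 genes, where on average 1078 genes passed for pwo1 and 1733 for crwn1 crwn2, fewer than the 1239 and 1935 listed. With an assumed 15000 genes the same-direction genes numbered 61.8 on average and at most 82, with a mean r of 0.09. With the sign turned 45 would be observed, which is below the maximum of these simulations. The opposite genes would then number 463, against averages of 30.6 with 27550 genes and 54.2 with 15000. The covariance of the fold changes was 1.23, compared with 0.035 simulated for shared controls in the same genes. All 508 genes were selected for passing in both tables, which raises both r and the covariance, and part of the excess may come from the shared controls, which could not be split.

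**Figure D2:**
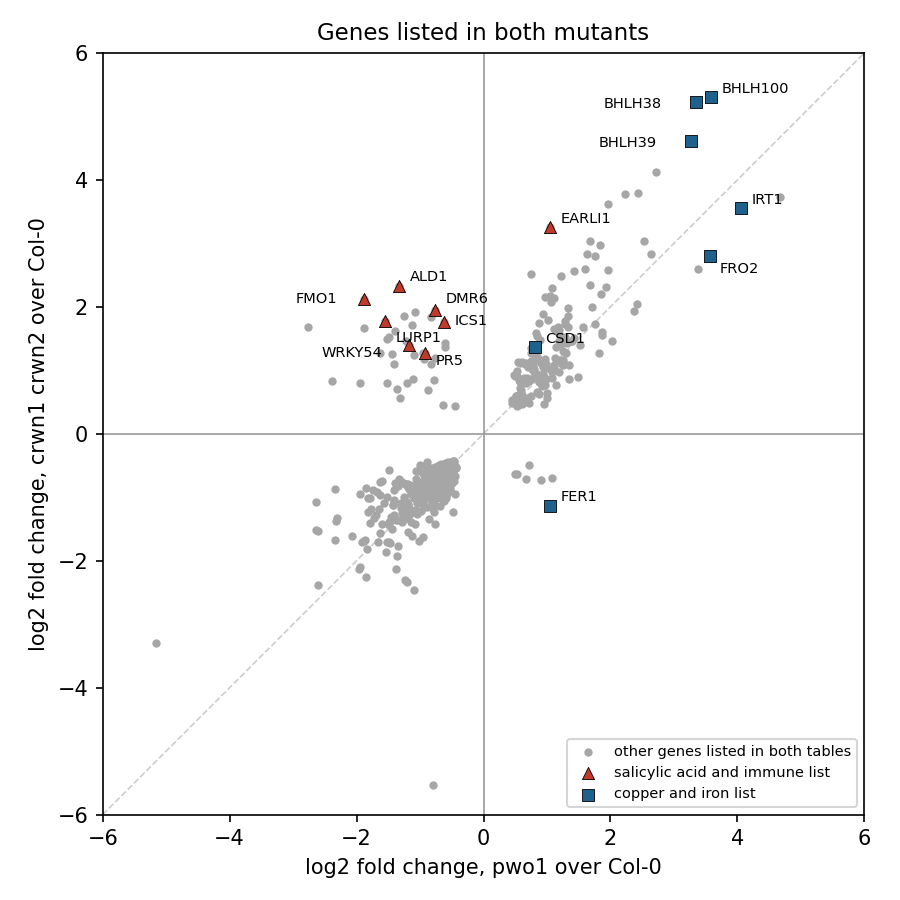
Log2 fold change over Col-0 in pwo1 (horizontal axis) against that in crwn1 crwn2 (vertical axis) for the 508 genes listed for both mutants, 1 point per gene without error bars, with members of the salicylic acid and immune list as triangles, of the copper and iron list as squares, and the dashed line marking equal change. Most points, 463 of 508, lie in the quadrants of equal direction, while 7 of the 8 immune genes lie in the quadrant lower in pwo1 and higher in crwn1 crwn2, and with the sign of the pwo1 table turned 45 of 508 and 7 of 8 would share a direction.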

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

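The tests in this part were chosen after the fold changes had been seen. Among genes listed for both mutants, 45 had opposite directions, and each of them differed between the mutants at an adjusted p under the threshold. That outcome follows almost by construction, because both values had already passed the authors' tests.

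Salicylic acid genes stood out among them. Of the 8 members of that list shared by the mutants, 7 went down in pwo1 and up in crwn1 crwn2 (PR5, ICS1, WRKY54, FMO1, ALD1, DMR6 and LURP1), and EARLI1 went up in both. Among the other 500 shared genes 38 were opposite, a share of 7.6% (two-sided Fisher's exact p = 2.04e-07, adjusted p = 1.02e-06 over 5 lists). Members of a list can change together and are not independent, so these p-values are likely too small. An offset between the tables would move all genes alike but turn the direction only of genes with small changes of their own. The concentration in this list therefore does not decide on an offset. All 7 were opposite by Cuffdiff too, with -1.87 in pwo1 and 2.19 in crwn1 crwn2 for FMO1 and -0.51 and 1.78 for ICS1. For these 7 genes the direction therefore did not differ between the 2 tools. Listing in both tools nearly guarantees that outcome, so it is no separate support for the pattern. In pwo1 the edgeR p-values of PR5, ICS1 and ALD1 were 0.0022, 0.0024 and 0.0028. With a p under 0.001 in both tools, 4 members of the list stayed lower in pwo1, without PR5, ICS1 and ALD1. The sign of the pwo1 table is read from its header alone, and with it turned these 7 would be alike and 463 of the 508 shared genes opposite. A difference in harvest time, plates or microbial load between genotypes was not tested and stays open, as does the mutated gene itself.

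FER1 was also opposite, with a difference of -2.19 on the log2 scale between crwn1 crwn2 and pwo1 (95% interval -3.03 to -1.34, adjusted p = 4.70e-06), though it overlaps another annotated gene. A set of 5 genes of iron uptake or its regulation was higher in both mutants, namely IRT1, FRO2, BHLH38, BHLH39 and BHLH100. The set was chosen after the values were seen, so their common direction follows from the choice. Of the same list, BHLH101 was listed only for crwn1 crwn2, at 1.92, and the regulator FIT for neither mutant. A candidate explanation is that the Col-0 libraries alone stood apart in iron status: with errors taken as independent, 0 of these genes differed between the mutants (adjusted p from 0.24 to 0.94, 95% intervals from -1.91 to 3.68). With errors correlated at 0.5 through the shared Col-0 libraries, an assumed value, 2 differed, BHLH38 and BHLH100 (smallest adjusted p = 0.023), both larger in crwn1 crwn2. Col-0 alone would give equal fold changes, so it is less apt for these 2, and for the set it cannot be told apart from a response in both mutants. Iron shortage in the plants predicts less ferritin, and in the authors' deposited tables FER1 at 1.06 and FER3 at 0.96 were higher in pwo1, while FER1 at -1.13 and FER4 at -0.85 were lower in crwn1 crwn2. FER1 and FER4 overlap other annotated genes, which leaves no certain value in crwn1 crwn2. FER3 overlaps none and goes against shortage in pwo1, but it is a single gene in a table whose sign rests on its header, so iron shortage stays open in both mutants.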

How the results depend on the processing

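The settings on both tools' p, Cuffdiff's fold changes, the assumed background and correlated errors were chosen after seeing the data. Stricter thresholds lowered the counts by construction. The upper bound on the adjusted p under 0.01 left 583 genes for pwo1 (31.4% higher, or 400 of 583 with the sign of the table turned), 1119 for crwn1 crwn2 (62.6% higher) and 189 shared with the same direction. A 2-fold threshold left 430, 782 and 146, Cuffdiff's 2-fold threshold 431, 774 and 140, and a p under 0.001 in both tools 812, 1272 and 247. Under these 4 settings 88.3% to 89.7% of the shared genes had a common direction, which with the sign of the pwo1 table turned would be the shares with opposite directions. Gene lists past the threshold fell to 7 with the 2-fold threshold, all 7 also past it without. The jasmonate list in pwo1 lost its call under the adjusted p bound (adjusted p = 0.22), the 2-fold threshold (0.15), the stricter p (0.31) and the background of 15000 genes (0.31). The cold list in pwo1 lost it under the adjusted p bound (0.48) and the stricter p (0.23). With the 2-fold threshold the pwo1 calls were lost for clock (0.074), flavonoid (0.061), glucosinolate (1) and leaf lists (1). The glucosinolate list in crwn1 crwn2 lost its call under the adjusted p bound (0.18), the 2-fold threshold (0.53) and the stricter p (0.21), and the mutated genes as a list with the assumed background (0.13). Stricter thresholds leave fewer members, and a smaller background raises the expected number, by construction. The other 58 checks of lists kept their side of the threshold. Named genes kept their direction in 106 checks with Cuffdiff's fold changes, which listing in both tools nearly guarantees. Shared genes that differ between the mutants numbered 61 with independent errors and 96 with errors correlated at 0.5, which are smaller for a difference by construction. No paired analysis was possible because the tables carry no replicate numbers. Leaving out replicates, other splits of the libraries, a filter on expression level, other pseudocounts, other count models and a joint fit were not run, since the tables hold no values per library and no levels. Restricting the correlation to genes called in both changes nothing, as all are. The unknown depth limits what an unlisted gene can show.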

Other observations

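Among the listed genes, some other families differed in direction from the rest, by family names in the reference annotation and a two-sided Fisher's exact test of higher against lower within each table, adjusted over 40 tests chosen after the tables were seen. All counts are of listed members, a small part of most families, and whether a family was listed more often than other genes was not tested. In crwn1 crwn2 all 17 listed WRKY transcription factors (adjusted p = 0.0016) and all 16 listed NAC factors (adjusted p = 0.0016) were higher. Listed receptor-like kinases were higher in 50 of 63 cases (adjusted p = 0.0016), disease resistance proteins of the NBS-LRR type in 20 of 22 (adjusted p = 0.0051) and heat shock proteins in 10 of 10 (adjusted p = 0.026). Listed SAUR and other auxin-responsive genes were lower in 24 of 26 cases in pwo1 (adjusted p = 0.0016) and in 18 of 23 in crwn1 crwn2 (adjusted p = 0.0058). Listed light harvesting and photosystem genes were lower in 29 of 33 cases in pwo1 (adjusted p = 0.0019) and in 17 of 22 in crwn1 crwn2 (adjusted p = 0.0090). In pwo1 9 of 10 listed ERF/AP2 factors (adjusted p = 0.012), 5 of 5 listed peroxidases (adjusted p = 0.042), 7 of 8 listed ribosomal protein genes (adjusted p = 0.041) and 11 of 14 listed lipid transfer protein genes (adjusted p = 0.041) were higher. The reference annotates 108 ERF/AP2 factors, 67 peroxidases, 376 ribosomal protein genes and 133 lipid transfer protein genes. Directions in pwo1 rest on the header's sign, and with it turned the listed SAUR and light harvesting genes would go opposite ways in the mutants. Members of a family can share reads and are not independent.

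Of 14 copper-responsive genes, 6 were listed for crwn1 crwn2, with copper-shortage genes lower and their microRNA targets higher in 6 of 6. The set and its directions were written after values were seen and no enrichment was tested, so this decides nothing about copper status. In the authors' deposited table FSD1 was at -1.21, FRO4 at -1.95 and the microRNA genes MIR398C and MIR408 at -1.58 and -1.40, while CSD1 and CSD2, known targets of the miR398 family, were at 1.37 and 1.40. Cuffdiff gave -4.74 and -4.24 for MIR398C and MIR408 in the authors' deposited table, so the size of those changes depends on the tool, and CSD1 and MIR408 overlap other annotated genes.

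Neighbouring listed genes tended to change in the same direction, a hypothesis whose first test was fixed before its result was seen. Of 114 adjacent pairs of protein-coding genes both listed for pwo1, 78.1% had the same direction, against a median of 50.9% when directions were permuted. For crwn1 crwn2 it was 72.4% of 199 pairs against 50.8%. Leaving out pairs with the same description or overlapping bodies, a test added after the first result, left 71.6% of 88 pairs and 67.7% of 155 pairs, so reads shared between such copies are unlikely to be the whole cause. The permutation p was 0.0001 in all 4 tests, the smallest that 10000 permutations can give. Related copies with different descriptions and co-regulated neighbours stay open.

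Transposon genes were listed in small numbers. In pwo1 4 of 11 were higher (one-sided Fisher's exact p = 0.76), which decides nothing at this number. In crwn1 crwn2 5 of 16 were higher (one-sided Fisher's exact p = 0.99). The share that was lower exceeded that of the other listed genes (one-sided Fisher's exact p = 0.037, not adjusted). That test and its direction were added afterwards. It covers only the 16 listed genes, so it does not decide on a release of the class as a whole. It does not speak for single genes, as the copia-like gene AT5G35935 was at 6.38 in the authors' deposited table. The tests of higher transposon genes, of the mutated loci and of the tools were fixed before their results were seen, except that each gene was counted once only afterwards. Within 50 genes on each side of the mutated locus, 4 genes were listed around PWO1 against a median of 4 over all windows, and 10 around the richer of the CRWN1 and CRWN2 loci against a median of 7, which is above 82.0% of windows, so linked changes were neither shown nor excluded. Fold changes of edgeR and Cuffdiff differed by more than 1 for 19 genes, of which 68.4% overlap another annotated gene, compared with 23.9% of the other 2640 genes, each counted once (one-sided Fisher's exact p = 5.46e-05).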
